A study of Drosophila melanogaster with 2 samples.

How the data were processed

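The material was chromatin from whole embryos of Drosophila melanogaster, 0 to 14 h old and of mixed sex, from a transgenic line in which GFP is fused to the C-terminus of the CG8388 product. Chromatin was sheared by sonication, and immunoprecipitation used an antibody against GFP, per the labels. Both libraries belong to a single group, and the labels number them as biological replicates 2 and 3. No untagged, mock or input library was analysed here.

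The deposited data are 4 peak lists in narrowPeak format on the dm6 assembly, with 1 list per replicate, 1 list for the pooled replicates and 1 list of peaks that passed the authors' irreproducible discovery rate (IDR) threshold, per the file headers and accompanying notes. Those notes also state that peaks were called with a control alignment. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The signal value of each peak is the authors' own, deposited on a scale that is not stated, and it was used only to rank peaks within a list. The deposited −log10 q-value of each peak was only inspected, since 4269 pooled peaks share its highest value. Summit positions were taken from the offset column as deposited. Both replicate lists and the pooled list hold exactly 30000 peaks, so their length is not a measure of binding. All 6075 thresholded peaks occur unchanged in the pooled list and are its 6075 highest by signal, so the remaining 23925 pooled peaks served as lower-ranked peaks. Peak lists carry no read totals, so the depth of either library is unknown and intervals cover counting error only.

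Gene models came from Ensembl release 115 and sequence from the RefSeq copy of Release 6 of the genome, which is the assembly of dm6. Between the Ensembl and RefSeq gene tables, 99.98% of 17683 genes matched by symbol had identical coordinates, and 0 peaks ran past a chromosome end. Coordinates are 1-based. Transposable elements were left out of the gene models. A summit was placed in 1 class in the order promoter (within 500 bp of a transcription start site, TSS, of a protein-coding gene), 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic.

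Replicate overlap was the share of peaks that overlapped a peak of the other list by at least 1 bp, set against 1000 shuffles within chromosomes with a permutation p (one-sided). Shares of peaks, genes or sequence windows were compared with two-sided Fisher exact tests and Benjamini-Hochberg adjustment within each family, at a threshold of 0.05. Gene lists were tested for the share of members with a thresholded summit within 500 bp of any of their TSSs. Protein-coding lists were set against all other protein-coding genes of the 6 arms, and RNA gene classes against all other annotated genes. In all, 25 lists were fixed and 24 could be tested, because the annotation has 0 genes in a microRNA class. Current symbols replaced 7 older ones after the annotation was seen. Consensus matching covered 29 motifs within 50 bp of summits against windows of equal width centred 400 bp to each side. For k-mers, all 8-mers were ranked on 2L, 3L and X, and the leading 10 were tested on 2R and 3R. Intervals of shares are Wilson 95% intervals, and those of odds ratios are Woolf intervals with a continuity correction. Fisher tests treat peaks and genes as independent, which neighbouring peaks and genes are not, and with a single group no p-value compares conditions.

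Peaks and genes were named by a rule: the 20 thresholded peaks of highest signal by the protein-coding gene with the nearest TSS, up to 4 members of each list past the threshold, up to 2 members of other lists, and always CG8388, the nearest 2 protein-coding genes on each side and white. A gene that the rule takes is not reported here. Groups, tests, gene lists, motifs, the naming rule and most alternatives were fixed before the data were examined. Alternatives varied the promoter window, the overlap rule, the backgrounds, the k-mer length, the number of peaks and the replicate used. Added after seeing the data were windows matched on GC content, microRNA genes taken by symbol, and the thresholded peaks found among the leading peaks of both replicates. Adding microRNA genes leaves the counts of the other lists unchanged and alters only their p-value adjustment, though it is counted among the settings.

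The statistics were tested on simulated data. For the overlap, a planted share of 59.8% of 6075 peaks was measured as 62.8%, chance overlaps included, and 7.5% of 40 unrelated lists had p under 0.05. In the gene list simulation, 99.8% of planted lists and 0.8% of unplanted lists were called. The 4 planted lists had 32 to 86 members and genes were drawn independently. These rates therefore do not carry over to smaller lists or to genes that share peaks. Among 29 motifs, 0 were called at random positions, and a planted 8-mer ranked first on the discovery arms. Real summits had lower GC content than their flanks (31.6% against 43.9%), which random positions do not. The motif and k-mer simulations therefore do not address calls that arise from base composition. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.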

Results

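CG8388 occupancy was profiled by ChIP-seq, in which DNA bound by a protein is precipitated and sequenced, in whole fly embryos that carry CG8388 fused to GFP. The data comprise 2 libraries of 1 group, replicates 2 and 3, with 30000 listed peaks each. A thresholded list of 6075 peaks and a pooled list of 30000 peaks draw on both libraries. Read totals are not part of the peak lists, so the depth is unknown. The design holds no second condition, and the comparisons address how far the replicates shared peaks, where the peaks lie and which genes and sequences they mark.

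Most of the leading peaks were shared between the replicates. The 2 highest peaks of the thresholded list, at the promoters of CG15771 on X and CG13919 on 3L, ranked 1 and 2 in each replicate. All 20 leading thresholded peaks stood within the first 100 of both replicate lists, but that list was derived from the same libraries, so these ranks are not independent evidence of agreement. Of the 6075 highest peaks of replicate 2, 76.4% (Wilson 95% interval 75.3 to 77.4) overlapped the 6075 highest of replicate 3, and the share in the other direction was 73.8% (72.7 to 74.9). Shuffled peaks overlapped in 2.89% ± 0.222 (SD over 1000 shuffles), and the permutation p was 0.000999, the smallest that 1000 shuffles can give (one-sided). Across the whole lists, 63.3% of replicate 2 peaks and 61.9% of replicate 3 peaks were shared, against 15.5% in shuffles. The overlap of the thresholded list with the leading peaks of both replicates was 73.9% (72.8 to 75), or 4490 peaks. That share is likewise not independent evidence.

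Promoters held most of the strongest peaks. Of the 20 leading peaks, 14 lay within 500 bp of a TSS of a protein-coding gene and 6 were on X. The highest, with a signal of 27855, spanned X from 5754786 to 5756346, with its summit at -110 bp from the nearest TSS of CG15771 (FBgn0029801). The next, with a signal of 21195, spanned 3L from 1644819 to 1645899, with its summit at -132 bp from the TSS of CG13919 (FBgn0035248). Promoter peaks also marked spidey, Top1 (DNA topoisomerase I), Imp (an RNA-binding protein), POSH, clu, CG5946, CG11791, px, CG14100, Ugalt (a UDP-galactose transporter), Art3 (an arginine methyltransferase) and CG18549. The intronic peaks among the 20 were nearest to hwt, Ssdp, bmm (a triglyceride lipase) and CG11050, and the intergenic ones to bgm and blo. The blo summit lay 10730 bp from the TSS.

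Over the whole thresholded list, 37.0% of summits (Wilson 95% interval 35.8 to 38.2; 2249 of 6075) were in promoters, compared with 22.9% (22.4 to 23.5) of the 23925 lower-ranked pooled peaks. The odds ratio was 1.98 (1.86 to 2.10; Fisher exact p = 3.25e-105), and summits shuffled within chromosomes gave 11.4% ± 0.401 (SD). Promoter summits were mostly upstream, with 82.5% on the upstream side of the nearest TSS and a median offset of -122 bp. Coding exons were nearly empty of thresholded summits, with 14 of 6075 (0.230%, 0.137 to 0.386) compared with 2.31% of lower-ranked summits, although they make up 13.3% of the bases of the 6 arms (adjusted Fisher exact p = 9.72e-37). Introns held 40.1% of thresholded summits and 44.4% of lower-ranked ones (adjusted Fisher exact p = 1.84e-09), and intergenic sequence 18.9% and 25% (adjusted p = 1.71e-23). Shares in 5' UTRs (0.626% against 0.978%), 3' UTRs (1.32% against 2.14%) and other exons (1.78% against 2.23%) were also lower, with adjusted p of 0.0114, 2.98e-05 and 0.0325. The coding exon share was 0.181% without replicate 2 and 0.461% without replicate 3. The classes are exclusive, so a higher promoter share lowers the others.

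**Figure D1:**
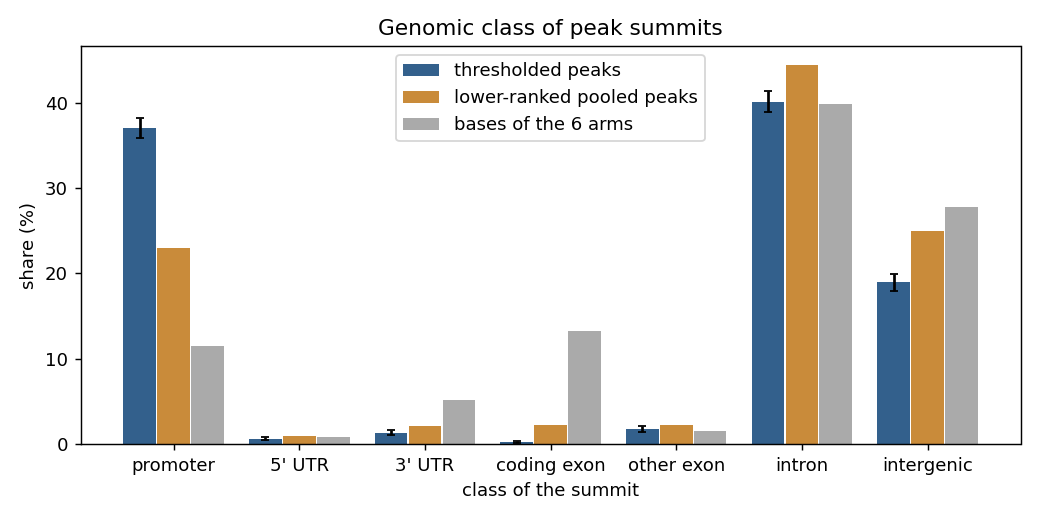
Share of summits (%) by genomic class for the 6075 thresholded peaks (blue, with Wilson 95% intervals), the 23925 lower-ranked pooled peaks (orange) and the bases of the 6 arms (grey). Promoters hold 37.0% of thresholded summits and coding exons 0.230%.

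The promoter share was highest at the strongest peaks. Among the 1215 peaks of highest signal, 47.98% (45.2 to 50.8) had promoter summits, compared with 33.3% (30.7 to 36.0) among the 1215 of lowest signal, a difference of 14.7 percentage points (Fisher exact p = 2.39e-13, two-sided). The other 3 bins of 1215 peaks held 36.8%, 34.2% and 32.8%. Matches to the A/T-only 8-mer ATTTAAAA fell from 9.14% to 5.27% of summits between the strongest and the weakest bin (Fisher exact p = 0.000286). Summit GC content rose from 29.6% to 33.8% between the same bins, so this trend cannot be told apart from a change in base composition. Overlap with the leading peaks of both replicates was 99.8% in the strongest bin and 17.4% in the weakest, partly because all these lists were limited to the same number of peaks. The promoter difference was 5.84 points without replicate 2, within the leading peaks of replicate 3 alone (Fisher exact p = 0.00402), and 19.8 points without replicate 3 (Fisher exact p = 2.39e-23). The k-mer difference was 4.86 and 2.39 points in the same sets.

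**Figure D2:**
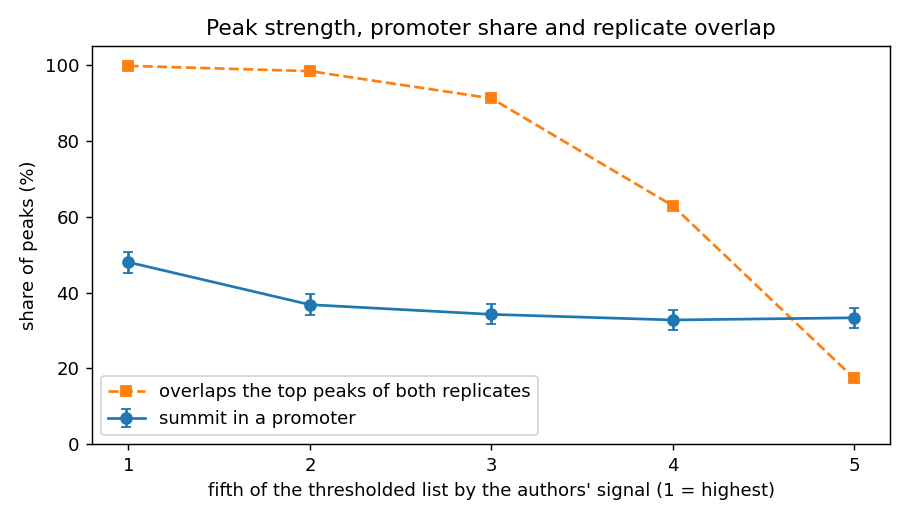
Share of peaks (%) with a promoter summit (circles, Wilson 95% intervals) and share overlapping the leading peaks of both replicates (squares) in 5 bins of 1215 thresholded peaks ordered by signal, bin 1 highest. Promoter share falls from 47.98% to 36.8% between bins 1 and 2 and lies between 32.8% and 34.2% in the others.

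All 4 peak lists were confined to arms 2L, 2R, 3L, 3R, 4 and X. Relative to protein-coding TSSs, thresholded peaks were over-represented on 3L, with 22.4% of peaks and 19.3% of TSSs (odds ratio 1.20, adjusted Fisher exact p = 9.58e-07), and under-represented on 2R, with 16.7% and 20.4% (0.781, adjusted p = 8.25e-10). Chromosome 4 carried 26 peaks, or 0.428%, against 0.736% of TSSs (adjusted Fisher exact p = 0.0169). Y and unplaced sequences, with 23 and 19 TSSs, have 0 peaks in all 4 lists, so the test of thresholded peaks there says nothing about binding. With the lower-ranked pooled peaks as background, 0 arms differed by the adjusted Fisher exact test and 1 at an unadjusted p under 0.05 (2L, p = 0.0397), and 3L had the smaller share of thresholded peaks (22.4% against 23.3%, adjusted p = 0.285). The call on chromosome 4 was also lost without either replicate (adjusted p of 0.117 and 0.331).

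Ribosomal protein genes stood out among the gene lists. No untagged or mock library was analysed, so CG8388 binding there cannot be told apart from signal that does not depend on it. Of 86 genes for cytosolic ribosomal proteins, 72 (83.7%) had a thresholded promoter summit, compared with 19.97% of other protein-coding genes (odds ratio 20.6, 11.4 to 35.3; adjusted Fisher exact p = 4.17e-35). Strong promoter peaks among them were at RpL34b (3R from 9401180 to 9401564), RpL7 and RpS27, with signals of 863, 727 and 638. Of 73 mitochondrial ribosomal protein genes, 31 (42.5%) had one (odds ratio 2.91, 1.84 to 4.64; adjusted Fisher exact p = 5.28e-05), led by mRpS10, mRpL41, mRpS23 and mRpL23. The mRpS10 summit, with rank 19 in the thresholded list, is the same peak that lies nearest to Art3, on 3R from 15229340 to 15229736. The call for cytosolic ribosomal proteins held in all 9 other settings, and that for mitochondrial ones was lost with the 3037 highest peaks (adjusted p of 0.439) and with the nearest TSS (0.888, the highest of its settings, with 4.81e-05 the lowest). That lowest value came with microRNA genes added, a setting that changes only the p-value adjustment of these lists.

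Genes of the Notch signalling pathway also carried promoter peaks more often, in 10 of 19 members (52.6%; odds ratio 4.36, 1.80 to 10.4; adjusted Fisher exact p = 0.00542). The leading members were E(spl)m7-HLH, gro (a co-repressor), E(spl)m3-HLH and fng (a glycosyltransferase that modifies Notch), with signals of 981, 972, 902 and 874. The peaks of E(spl)m7-HLH, E(spl)m3-HLH, gro, E(spl)mdelta-HLH and E(spl)mbeta-HLH, 5 of the 10, lie close together on 3R, between 25997048 and 26042667, and the last 2 of these genes are named after their values were seen. Among insulator and promoter-binding proteins, 9 of 20 genes had a promoter peak (45%; odds ratio 3.21, 1.37 to 7.65; adjusted Fisher exact p = 0.0298), led by Chro, Cp190, M1BP and Dref. The Chro peak, on 3L from 22878705 to 22879104, had rank 24. The Dref peak, on 2L from 9967194 to 9967467, is also that of RpL13, whose TSS lies nearer, and it counts in both lists. The Notch call was lost with a 250 bp window (adjusted p of 0.419) and among genes with a pooled promoter summit (odds ratio 1.87, adjusted p of 0.432; range over settings 0.00216 to 0.432). The insulator call was lost in 6 of 9 other settings, without replicate 2 among them (odds ratio 2.00, adjusted p of 0.307; range 0.0251 to 0.459).

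Several gene lists had no thresholded promoter peak. These were 70 cuticle protein genes (such as Cpr100A and Cpr11A), 119 odorant and gustatory receptor genes (such as Gr10a and Gr21a) and 111 replication-dependent histone genes (such as His1:CG31617), with adjusted p of 1.11e-06, 2.96e-11 and 1.22e-10. For counting error only, a count of 0 allows a share of up to 4.29%, 2.52% and 2.70%. These limits, and that of the synaptic genes below, are 3 divided by the list size and not Wilson limits. Some cuticle genes had a promoter summit among the leading peaks of a single replicate. Their odds ratios were 0.0533 without replicate 2 and 0.115 without replicate 3 (adjusted Fisher exact p of 1.36e-05 and 0.000145). The histone genes lie in near-identical tandem copies, and 0 of the 111 had a promoter summit even in the pooled list. Whether a peak could be called there is unknown, so the p-value and limit of the histone list say nothing about binding. Synaptic genes (such as ChAT, Gad1, Rab3 and Rdl) had 0 of 19 (adjusted Fisher exact p = 0.0496; up to 15.8%). That call was lost in 8 of 9 other settings, with adjusted p from 0.0470 to 0.368. The setting that kept it added microRNA genes, which changes only the p-value adjustment of this list. Of the RNA classes, 23 of 290 tRNA genes (7.93%; adjusted Fisher exact p = 1.93e-05) and 16 of 269 snoRNA genes (5.95%; adjusted p = 3.15e-07) had a thresholded promoter summit, compared with 17.4% of other annotated genes for each. In the pooled list, 183 of the tRNA genes and 47 of the snoRNA genes had a promoter summit. Most tRNA genes thus had a listed peak, but seldom one above the threshold. The tRNA genes with a thresholded summit shared 17 peaks, led by that at tRNA:Tyr-GTA-1-8 (rank 129), and the snoRNA genes shared 13, led by that at snoRNA:Psi28S-2949 (rank 477). The tRNA odds ratio was 0.979 among the leading peaks of replicate 3 alone (adjusted p of 1.00; range over settings 9.18e-16 to 1.00) and 0.170 among those of replicate 2 alone, and the call was also lost with the nearest TSS (0.712, adjusted p of 0.102). The snoRNA call was lost with a 1000 bp window (odds ratio 0.892, adjusted p of 0.802; range 4.58e-13 to 0.802) and among genes with a pooled promoter summit (0.760, adjusted p of 0.761).

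The other 14 lists did not pass. Their values were 8 of 32 for proteasome subunits (Rpn3, Rpn5), 14 of 78 for oxidative phosphorylation (ND-ASHI, ND-MWFE), 1 of 8 for Hox genes (Dfd), 5 of 34 for anteroposterior patterning (nkd, ci) and 3 of 26 for dorsoventral patterning (tin, htl), which exceeded the background when peaks were assigned to the nearest TSS (odds ratio 4.08, adjusted p of 0.00214; range over settings up to 1.00). Polycomb and trithorax genes had 7 of 25 (ph-p, E(z)), heat shock genes 6 of 18 (Hsp27, Hsp83), and cell cycle and replication genes 12 of 34 (CycE, Dp). Neuroblast genes had 3 of 19 (elav, insc), muscle structure 3 of 18 (sls, Tm1), germline and piRNA genes 8 of 20 (cuff, piwi), the ecdysone pathway 3 of 17 (Eip75B, EcR) and snRNA genes 4 of 32. The chorion list had 1 of 11, and that member was Cp190, an insulator protein that the list's symbol pattern took in. Adjusted p ranged from 0.100 for germline and piRNA genes to 1.00. Some odds ratios moved with the replicate used, without passing. Without replicate 2 and without replicate 3, the ecdysone pathway had 2.02 and 0.843 (0.838 with both). Polycomb and trithorax genes had 2.47 and 2.22 (1.52 with both), and snRNA genes 0.640 and 0.322 (0.684 with both). Germline and piRNA genes passed with a 1000 bp window (odds ratio 3.15, adjusted p of 0.0439) and with peaks found in both replicates (3.67, 0.0185; range over settings up to 0.334), and heat shock genes with the 3037 highest peaks (3.68, 0.0455; range up to 1.00). In all, 10 of 24 lists passed, the histone list among them, and 11 had an unadjusted p under 0.05. When only genes with a pooled promoter summit formed the background, 3 lists passed. The cytosolic and mitochondrial ribosomal proteins had thresholded promoter peaks more often, and the tRNA genes less often (odds ratio 0.206). The cuticle and receptor calls were lost there (adjusted p of 0.0796 and 0.0680), with only 7 and 8 such genes.

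**Figure D3:**
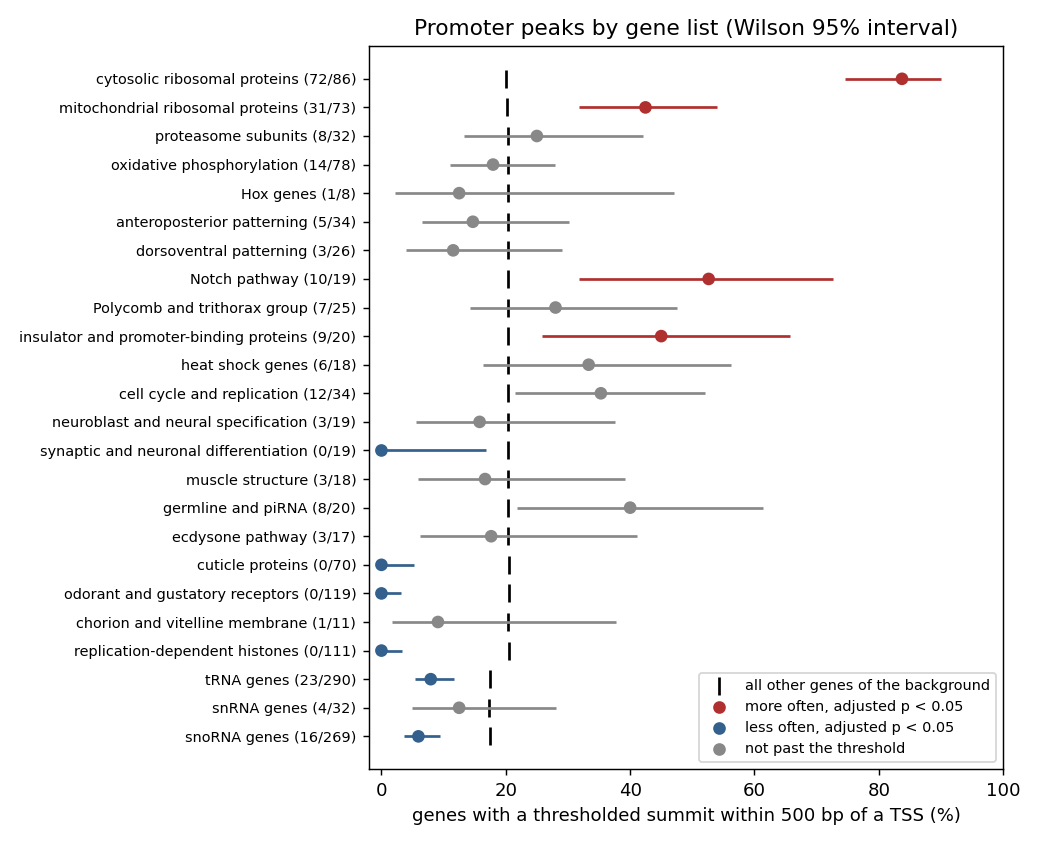
Share (%) of the genes of each list with a thresholded summit within 500 bp of a TSS (points, Wilson 95% intervals), beside the share among all other genes of the background (black ticks), with counts in parentheses. Red lists had promoter peaks more often and blue lists less often at an adjusted p under 0.05; cytosolic ribosomal protein genes lie highest, at 83.7%.

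Summits lay in A/T-rich sequence. GC content within 50 bp of thresholded summits was 31.6% ± 9.34 (SD over 6075 peaks), compared with 43.9% ± 7.25 at 400 bp to either side, and it was lower at the summit in 83.1% of peaks. Against these flanks, 11 of 29 consensus motifs were more frequent at summits and 7 less frequent. Insulator motifs were among the former, with CTCF at 0.774% of summits against 0.230% of flanks (odds ratio 3.38, adjusted Fisher exact p = 6.38e-07) and Su(Hw) at 1.27% against 0.436% (2.93, adjusted p = 5.88e-09). So were the promoter elements DRE (2.05), core promoter motif 1 (2.62), motif 6 (3.28) and motif 7 (1.46), the TATA box (2.36), and the Hox (2.04), GATA (1.65), Mef2 (1.77) and CATATG (1.23) consensuses, given as odds ratios. The GAGA factor motif GAGAGAG was less frequent at summits (0.905% against 2.68%; odds ratio 0.331, adjusted Fisher exact p = 3.38e-16), as were CACGTG (0.451), CAGCTG (0.556), CAGGTG (0.477), and the E2F (0.455), Scalloped (0.550) and initiator (0.884) motifs. Without replicate 2 and without replicate 3, the odds ratios were 0.687 and 0.233 for GAGAGAG and 6.47 and 1.77 for core promoter motif 1, and that of CTCF was 2.22 without replicate 3. The CTCF call was lost with the 3037 highest peaks (2.29, adjusted p of 0.0525) and against lower-ranked summits of the same class (1.09, adjusted p of 0.990; range over settings 5.11e-14 to 0.990).

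Several of these results differed when genomic windows matched on GC content replaced the flanks as background. Of the 11 motifs, 6 were still more frequent at summits, with odds ratios of 11.8 for CTCF (adjusted Fisher exact p = 5.11e-14), 6.82 for core promoter motif 1, 2.60 for motif 7, 1.43 for DRE, 1.23 for CATATG and 1.13 for GATA. The calls for Su(Hw) (1.42, adjusted p of 0.0609), motif 6 (1.24), Mef2 (1.37), the TATA box (0.913) and the Hox consensus (0.920) were lost, and the lower frequency of GAGAGAG was lost (1.27, adjusted Fisher exact p = 0.290), as was that of CAGGTG (0.906, adjusted p of 0.526), the initiator (0.968, 0.629), CACGTG (1.08) and E2F (1.04). CAGCTG changed from less to more frequent (1.61, adjusted Fisher exact p = 7.27e-05), Zelda (1.94) and Ets (4.01) motifs were more frequent only here, and Scalloped, alone of the 7, was still less frequent (0.750). Against flanks, Zelda was less frequent within 100 bp of summits (0.678, adjusted Fisher exact p = 0.0312). Of the motifs named, Mef2 was past the threshold in 1 of 9 other settings (adjusted p from 0.0179 to 0.533), the initiator in 3 (0.00281 to 0.764) and CATATG in 5 (0.00241 to 0.882), and core promoter motifs 1 and 7 in 4 each. Against lower-ranked summits of the same class, 3 motifs were more frequent, the Hox (1.82), GATA (1.36) and TATA (1.38) consensuses, and DRE was less frequent (0.704, adjusted Fisher exact p = 0.0125).

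**Figure D4:**
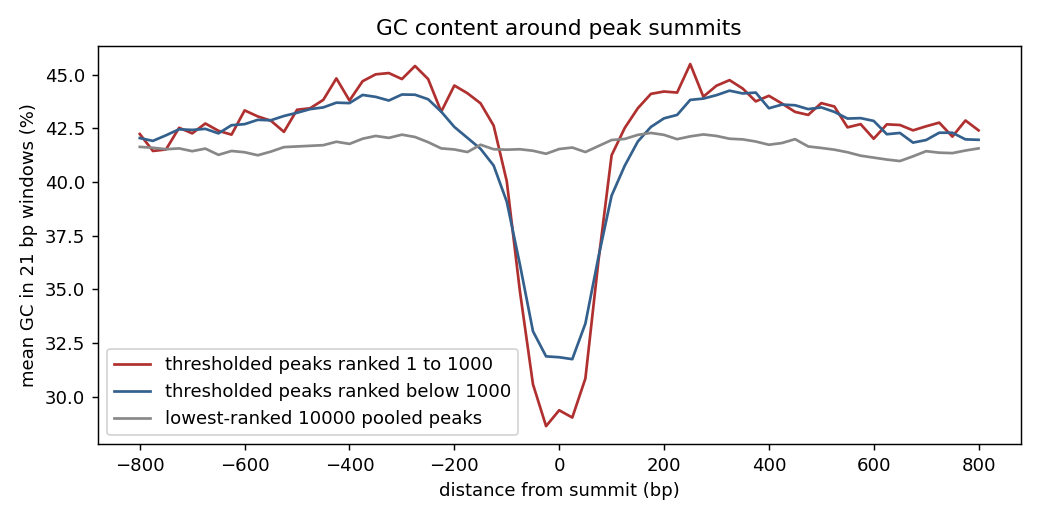
Mean GC content (%) of the sequence at distances up to 800 bp from the summit for thresholded peaks of rank 1 to 1000 (red), the other thresholded peaks (blue) and the 10000 lowest-ranked pooled peaks (grey). At the summit the lines lie at 29.4%, 31.8% and 41.5%.

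The leading 8-mers at summits were A/T-only. ATTTAAAA ranked first on 2L, 3L and X, and on the held-out arms 2R and 3R it occurred at 6.74% of 2419 summits, compared with 1.72% of 4838 flanks (odds ratio 4.14, 3.16 to 5.40; Fisher exact p = 9.18e-27). All of the leading 10 passed on the held-out arms, and at least 1 of them occurred at 33.4% of summits and 10.2% of flanks. GC content was 31.6% at summits and 43.9% in flanks, so A/T-only words can be more frequent at summits through base composition alone. Holding out arms cannot separate that from a preference for these words. With the windows matched on GC content, the leading 8-mer was CACTGTGC instead, at 1.53% of held-out summits against 0.227% of matched windows (odds ratio 6.82, 3.41 to 12.8; Fisher exact p = 5.91e-10). CACAGTGG and ACAGTGAG followed the same pattern there, at 1.32% against 0.227% and 1.03% against 0.124%.

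A weak peak lay at the tagged gene. CG8388 (FBgn0034062) lies on 2R from 16009401 to 16011438 on the minus strand, within the span of CG8389. A thresholded peak of rank 5406 covered its 5' end, from 16011369 to 16011768, with the summit 131 bp beyond that end. The same peak lies inside CG8389 (2R from 16008339 to 16013815) and is the only thresholded peak with its summit there. The summit ranked 6260 in replicate 2 and 5931 in replicate 3. Ufc1, on one side, had a thresholded summit of rank 3585. Tmem131 and Prosbeta1 had no thresholded summit, and their best ranks in the pooled list were 6481 and 11196. Within 20 kb of CG8388 there were 3 thresholded and 11 pooled summits, of which the strongest had rank 99 and lay 16882 bp from the gene. At white (w), an eye colour gene often used as a transgene marker, on X from 2790599 to 2796466, there was 1 pooled summit of rank 13249.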

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

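Windows matched on GC content, microRNA genes taken by symbol and the restriction to peaks found in both replicates were chosen after the result was seen. No paired analysis was possible because the design has a single group. Replicate overlap without a replicate, core promoter motif 1 outside promoters, the NRF1 motif against GC-matched windows and the histone list among genes with a pooled summit gave no value. All 25 alternative tests of the main results kept the direction and the side of the threshold, and of the alternative counts 22 stayed within a factor of 1.5 and 6 did not. Replicate overlap was tested one-sided, so its direction could not change. Each k-mer setting tested its own leading word, CACTGTGC with GC-matched windows, so these tests do not show that ATTTAAAA was kept. Replicate overlap ranged from 59.9% (reciprocal overlap) to 78.1% (fewer peaks), and promoter share from 28.2% (250 bp window) to 46.3% (1000 bp window). The number of chromosome categories that differed, 5 with Y and unplaced sequences, where all lists have 0 peaks, fell to 0 against lower-ranked pooled peaks and to 2 with the 3037 highest thresholded peaks. The number of gene lists, 10, fell to 3 when only genes with a pooled promoter summit were used, where fewer genes were tested. The number of motifs more frequent at summits, 11, fell to 3 against lower-ranked summits, to 6 at summits outside promoters and to 7 with the 3037 highest peaks. The cause was not tested, though the smaller sets also hold fewer peaks. With a single replicate, promoter share was 37.1% to 39.8%, the chromosome count 4 to 5, the list count 7 to 9, the motif count 8 to 10, the promoter trend 5.84 to 19.8 points and the k-mer trend 2.39 to 4.86 points. The k-mer odds ratio was 3.82 for ATATTTTA, the leading 8-mer without replicate 2, and 4.33 for ATTTAAAA, the leading 8-mer without replicate 3. Of the single lists, motifs and arms, 65 values lost their call, 10 gained one and 13 changed direction with a value past the threshold in at least 1 setting, and the cause was not tested. A further 38 odds ratios crossed 1 without passing the threshold in either setting. On 3L the share of 22.4% went from above to below its background with lower-ranked peaks. Dorsoventral patterning genes, which did not pass at promoters (odds ratio 0.510, adjusted p of 0.537), had an odds ratio of 4.08 with the nearest TSS within 5000 bp. Against lower-ranked summits the odds ratios of DRE and core promoter motifs 1 and 6 were 0.704, 0.606 and 0.900, and motif 7 had 0.654 outside promoters. With GC-matched windows, where 9 motifs were more frequent, the odds ratios were 0.913 (TATA box), 1.27 (GAGA factor), 1.94 (Zelda), 1.08 (CACGTG), 1.61 (CAGCTG), 0.920 (Hox) and 1.04 (E2F). MicroRNA genes taken by symbol had a promoter summit in 7 of 260 (2.69%; adjusted Fisher exact p = 1.81e-12), making 11 lists of 25, and peaks found in both replicates gave 9 lists and a promoter share of 37.3%. Depth is unknown, so whether more reads would add peaks at the lists with 0 cannot be judged.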

Other observations

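All tests given here were chosen after the result was seen, except those of GC content at promoters without a peak and of pooled peak counts near CG8388. The GAGA factor motif was sparse at the summits of the strongest peaks. In the 1000 highest thresholded peaks, GAGAGAG had 1 and 6 matches per 1000 peaks in the 50 bp bins on either side of the summit, 22 and 23 from 50 to 100 bp, 90 and 68 from 100 to 150 bp, 49 and 32 from 350 to 400 bp, and 57 and 54 from 400 to 450 bp, with no test of these bins. The thresholded peaks below rank 1000 had 10.4 and 12.4 next to the summit and 27.4 and 33.1 at 100 to 150 bp, and the 10000 lowest-ranked pooled peaks had 23.5 and 28.3 next to the summit and 23.0 and 22.8. Over all thresholded peaks, GAGAGAG from 50 to 150 bp away did not differ detectably from that at 400 bp (3.05% against 2.66%, odds ratio 1.15, adjusted Fisher exact p = 0.138). From 50 to 150 bp away, DRE occurred in 2.77% of windows against 0.996% at 400 bp (odds ratio 2.84, adjusted Fisher exact p = 6.77e-24), core promoter motif 7 in 2.70% against 0.897% (3.06, adjusted p = 1.58e-25) and the TATA box in 1.89% against 1.16% (1.64, adjusted p = 1.36e-05), while the initiator, at 8.82% against 9.29%, did not pass (0.945, adjusted p = 0.291). The TATA box was at 2.75% of summits, and windows beside summits were not tested against summits.

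The A/T-rich box at summits was deepest within 50 bp, was largely gone by 150 bp and was seen in promoter, intron and intergenic peaks alike, at 31.8%, 31.3% and 31.1% GC. The values argue against promoter composition alone, since promoters without a pooled summit had GC 8.14 percentage points higher (SE 0.234) at the same offsets. They also argue against avoidance of coding exons, since the drop was 12.1 points (SE 0.225) where summit and flanks were all intronic or intergenic. The drop at the 10000 lowest-ranked peaks was 3.35% of that at thresholded peaks, which argues against a caller that favours A/T equally at every peak. Over all 23925 lower-ranked pooled peaks, GC at the summit minus the flanks was -2.91 points, against -12.2 at thresholded peaks. An effect of the caller or read mapping that grows with peak strength was not tested and stays open. Library GC bias stays open, because the test of it decides nothing: GC at thresholded minus lowest-ranked peaks was -0.777 points (SE 0.109) from 75 to 200 bp from the summit, but -2.46 (SE 0.139) in the inner 50 bp of that range, where the box still lies, and 0.674 (SE 0.135) in its outer 50 bp. That range had replaced a first one over the whole 200 bp on each side (-3.84 points), which holds the box itself, and -0.777 was first read as in favour of the bias, until the same sign at both ends was required, a rule changed after the values were seen. No biological explanation was tested, as the design has no second group, and no input library was analysed here.

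A CACTGAGA word may mark a site of fixed orientation beside the A/T-rich box, while its spacing from the summit was not tested. Ranked on 2L, 3L and X, it was the leading 8-mer from 50 to 150 bp beside summits, and on 2R and 3R it occurred in 2.67% of 4838 windows against 0.124% at 400 bp, an odds ratio of 22.1 (9.29 to 44.99; adjusted Fisher exact p = 1.65e-30), which argues against a chance pick among 8-mers, although related words had been noticed on all arms beforehand. A repeated element that carries most of the matches is argued against by a median identity of 33.3%. That median is over the 15 bp on each side between pairs of the 311 matches. A repeat behind a smaller share of the matches need not shift the median, so it stays open. On the held-out arms, 93.8% of 129 matches (Wilson 95% interval 88.2 to 96.8; exact binomial p = 4.79e-27, two-sided) had the 3' side of CACTGAGA toward the summit, in line with a fixed orientation. Matches were not split into promoter and other peaks, and the windows at 400 bp are not matched on GC content. Of promoter summits, 82.5% lay upstream of the nearest TSS. At promoters, orientation toward the summit thus cannot be told apart from orientation relative to the TSS. Which protein, if any, reads the word was not tested.

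Extra copies of CG8388 in the transgene could raise reads around the gene and yield peaks there. The 11 pooled summits within 20 kb compare with a median of 10 over 13945 protein-coding genes, and 50.1% of these had fewer. Replicate 2 had 6 summits there and replicate 3 had 16, with fewer at 20.4% and 66.1% of genes, and no list exceeded its 95th percentile (26, 24 and 28), which argues against a local excess of peaks. Peak counts do not measure read height, so a modest rise in reads without added peaks stays open.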
